A study of Chrysanthemum x morifolium with 4 samples.

How the data were processed

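The series holds RNA-seq of total RNA from chrysanthemum leaves under 4 treatments, with 1 library per treatment. Per the labels' protocols, RNA was extracted with Trizol, libraries followed standard Illumina protocols, and each library was a mixture of leaves from 3 replicates of a treatment. Groups were taken from the treatment label of each sample, and each column of the table was tied to its sample by the sample title in the column name. The table gives, per the file headers, a count and an FPKM for each unigene in each library.

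The counts deposited by the authors are whole numbers, not normalized. They sum to 14024558 to 15781435 per library, which sets the precision of every ratio below, and a count of 0 is taken to allow up to 3 counts. No source used here names molecular identifiers, so intervals and limits taken from counts cover counting error only. The FPKM values deposited by the authors equal the count divided by the library's summed count and by a length that is the same in all 4 libraries (largest relative difference 2.04e-08). The lengths implied in this way run from 201 to 14975 bases with a median of 407. FPKM is therefore scaled by total counts. Every unigene listed has at least 1 count in some library (0 without).

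Per the submitters' processing notes, Bowtie 0.12.2 and Cufflinks were used, and the mouse build mm8 is named. The identifiers are those of assembled sequence components and carry no chromosome, and how a mouse build relates to them is not given in the sources used here. The assembler, the counting rule, the use of strand and the filters are likewise not given in the sources used here. In a plant with several similar genome copies, reads may be split between near-identical unigenes, and this affects single unigenes more than sets. No genome or annotation was used here, and no coordinates are given. The table pairs no unigene with a gene name, so 47 lists of cold, hormone, sugar, photosynthesis, clock and other genes, fixed before the data were examined as patterns on gene descriptions, could not be applied and have no result.

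The choices of comparisons, rule and alternatives were fixed before the data were examined, except where stated. With 1 library per treatment no count model was fitted to a pair of treatments. An additive model of acclimation and freezing over the 4 libraries leaves 1 residual degree of freedom. It was fitted after the data were examined, as an alternative, with edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment over the 48004 unigenes with at least 10 counts. It takes any interaction of acclimation and freezing as part of the spread, and tests each factor over both states of the other. On simulated counts with the fitted common spread (30.1%) it called 199 of 200 unigenes changed 8-fold by freezing and 7 unchanged ones. For acclimation, where none was changed, it called 0. The simulation gave every unigene the same spread and no interaction, so it does not show how the fit behaves where these differ. Libraries were scaled by TMM (edgeR 4.0.16 in R 4.3.3, factors 0.993, 0.976, 0.928 and 1.11 for control, acclimated, acclimated and frozen, and frozen without acclimation). For each comparison the ratio of scaled counts was given its exact (Clopper-Pearson) 95% interval from the binomial share of the counts of both libraries (scipy 1.17.1). A unigene was called higher or lower where that whole interval lay beyond 2-fold. Log2 ratios used a prior count of 0.5. Medians of sets are given also with unigenes at 0 counts set to the limit of 3 counts in that library. Abundance classes use the mean FPKM over the 4 libraries. The difference between a pair of freezing responses was given a 95% interval from the counting variance of 4 log2 counts (delta method).

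The rule on simulated data was checked with counts drawn from the real means and library sizes, with 200 unigenes of at least 100 counts changed by 4-fold or 8-fold. For acclimation against control (78314 unigenes) it recovered 100% of 4-fold and 100% of 8-fold changes with counting error alone and called 9 unchanged unigenes. With an assumed extra spread (coefficient of variation) of 20% between libraries it called 119 unchanged unigenes, and with 40% it called 2996, recovering 78% and 97%. For freezing without acclimation against control (81889 unigenes) the unchanged calls were 5, 117 and 3144, and for freezing after acclimation against acclimation (77713 unigenes) they were 10, 108 and 2914. For freezing after against freezing without acclimation (81786 unigenes) they were 17, 122 and 2939, and for the whole sequence against control (80023 unigenes) 12, 119 and 3039. The spread between plants is unknown here, so the number of calls that replicates would uphold is unknown too.

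Because comparisons with a common library share its chance values, the relation between responses was taken from pairs of ratios with no library in common. Overlaps are set beside the number that independent lists would share, and beside simulations of unchanged unigenes with counting error alone (20 draws) and with an assumed spread of 40% (10 draws). The rule for named items allowed, where no names are paired with identifiers, at most 2 unigenes that rose and 2 that fell. These were taken from the first comparison, acclimation against control, as those with a mean of at least 1 FPKM whose interval bound nearest to no change was farthest from it. Alternatives were scaling by total counts or by median-of-ratios factors (DESeq2 1.42.0), minimum counts or FPKM, a stricter and a looser interval rule, and a rule on the FPKM. The figures were drawn with matplotlib 3.10.9.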

Results

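RNA was sequenced from leaves of the chrysanthemum cultivar Jinba (Chrysanthemum x morifolium), raised from tissue culture and moved to pots before treatment. The study asked how the leaf transcriptome changes under low temperature, and what a spell of cold acclimation before freezing does to that change. Acclimation here means exposure to a low temperature above freezing, which raises the freezing tolerance of many temperate plants. There were 4 libraries, 1 per treatment. The first came from control plants, the second from plants acclimated at 4 °C for 24 h, the third from plants acclimated in that way and then frozen at -4 °C for 4 h, and the last from plants frozen at -4 °C for 4 h with no acclimation. Each library was made from the mixed leaves of 3 replicates, so the spread between plants was not measured, and no comparison of a pair of treatments below is tested or has a p-value. Every interval below on a share of counts or on a ratio between libraries covers counting error only. Intervals over unigenes treat unigenes as independent and likewise hold no spread between plants.

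The table listed 93837 unigenes, which are transcripts pieced together from the reads, by an assembly identifier. It paired none of them with a gene name, so the results below describe sets of unigenes by their level and their response. The libraries held 15781435 counts (control), 15179341 counts (acclimated), 14024558 counts (acclimated, then frozen) and 14345704 counts (frozen without acclimation). A count of 0 allowed a level of up to 0.190 to 0.214 CPM, taking 3 counts as the limit. Of all unigenes, 45833 (48.8%) had fewer than 10 counts over the 4 libraries, and these held 0.318% of all counts.

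The control leaves devoted more of their transcripts to a few very abundant unigenes than any of the 3 cold-treated libraries. The 100 most abundant unigenes of each library held 31.6% of counts in the control (exact 95% binomial interval 31.57 to 31.61%), 20.5% after acclimation (20.47 to 20.51%), 18.1% after acclimation and freezing (18.08 to 18.12%) and 19.8% after freezing alone (19.80 to 19.84%). A share of 50% of all counts lay in 669 unigenes in the control, 1094 after acclimation, 1114 after acclimation and freezing and 1286 after freezing alone. The particular 100 unigenes that led the control library, chosen on that library, held 17.4% of counts after acclimation, 14.1% after acclimation and freezing and 18.0% after freezing alone. The number of unigenes at 100 FPKM or more was 846 in the control, against 1109, 1156 and 1026 in the acclimated, the acclimated and frozen, and the unacclimated frozen library.

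**Figure D1:**
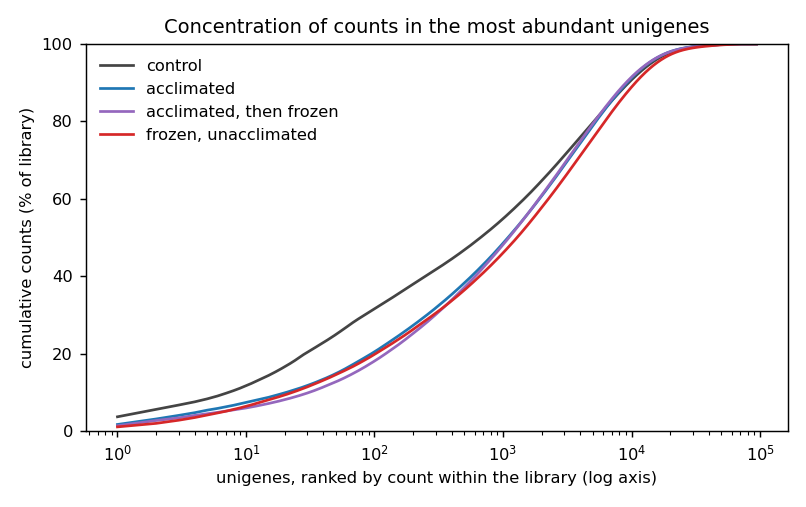
Cumulative share of each library's counts (vertical axis, percent) against the number of unigenes ranked by count within that library (horizontal axis, log scale), with 1 line per library. The control line runs above the other lines over the first 1000 ranks, reaching 31.6% at rank 100 where the other libraries lie between 18.1% and 20.5%.

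The first comparison asked what 24 h at 4 °C changed. Acclimated leaves differed broadly from the control, in both directions: 3751 unigenes were called higher and 3146 lower than in the control, 8.81% of the 78314 compared. The unigenes called higher made up 6.59% of the control library and 25.9% of the acclimated one, and those called lower went from 25.1% to 8.04%. Among the higher unigenes the median log2 ratio was 2.28, or 2.10 with unigenes at 0 counts set to the limit of 3 counts. Among the lower ones it was -2.45, or -2.15 with zeros at the limit. Abundant unigenes were called higher more often than lower (1650 against 794 at a mean of 10 to 100 FPKM, and 246 against 115 at 100 FPKM or more), whereas at 1 to 10 FPKM the counts were 1411 higher and 1599 lower, and under 1 FPKM 444 higher and 638 lower. A unigene was called where the whole 95% interval of its ratio, with libraries scaled by TMM, lay beyond 2-fold. The split between higher and lower was even enough to turn with the rule: 48.4% of calls were higher when the interval only had to exclude equal levels, and 46.8% under a rule of a log2(FPKM + 1) difference of at least 1.

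The strongest risers and fallers in this comparison differed in what freezing did to them. Unigene c109682.graph_c0 went from 23 counts (2.25 FPKM) in the control to 27538 counts (2798 FPKM) after acclimation, a log2 ratio of 10.27 (95% interval 9.72 to 10.96). It stood at 2171 FPKM after acclimation and freezing and at 468 FPKM after freezing alone. Unigene c94999.graph_c0 had 1 count in the control and 3994 counts after acclimation, a log2 ratio of 11.45 (9.57 to 17.35). It had 7763 counts after acclimation and freezing but 4 counts after freezing alone. Unigene c92928.graph_c0 had 514 counts in the control and 0 after acclimation, where the 95% interval put the log2 ratio at -7.04 or lower, and it had 1 count after acclimation and freezing and 64 after freezing alone. Unigene c100903.graph_c0 fell from 771 counts in the control to 2 after acclimation (log2 ratio -8.20, interval -11.56 to -6.65), and stood at 233 counts after acclimation and freezing and 646 after freezing alone.

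The second comparison asked what 4 h at -4 °C changed in plants that had not been acclimated. Fewer unigenes were called after freezing alone than after acclimation, and most of them were higher: 2479 were called higher and 1037 lower than in the control, 4.29% of the 81889 compared. Large changes leaned further to the higher side, with an interval wholly beyond 8-fold for 518 higher and 42 lower unigenes. After acclimation that limit was met by 326 higher and 166 lower unigenes, so freezing alone gave more of the large rises. The treatments also differed in length, 4 h against 24 h. The median log2 ratio was 3.35 among those called higher (2.66 with zeros at the limit) and -2.55 among those called lower (-2.03). Most of the higher unigenes were scarce in the control, with a median of 0.585 FPKM there and 7.53 FPKM after freezing, and 582 of them had no count in the control. Of the 1019 unigenes at a mean of 100 FPKM or more, 116 were called higher and 84 lower. The unigenes called lower held 20.9% of control counts and 6.90% of counts after freezing. Over the 23772 unigenes with at least 100 counts, the interquartile range of log2 ratios was 0.72, against 1.38 for acclimation. When the interval only had to exclude equal levels, 52.6% of calls were higher.

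The third comparison set leaves frozen after acclimation against acclimated leaves that were not frozen. It gave a similar number of calls, again mostly higher: 2687 unigenes were called higher and 720 lower, 4.38% of the 77713 compared. An interval beyond 8-fold was found for 455 higher and 23 lower unigenes. The median log2 ratio was 3.09 among the higher (2.60 with zeros at the limit) and -2.40 among the lower (-2.15). The higher unigenes had a median of 0.861 FPKM in the acclimated library and 7.68 FPKM after freezing, and their share of counts went from 2.66% to 13.7%. The lower ones held 3.87% of counts before freezing and 1.22% after. The lean towards higher calls belonged to large changes, since 48.0% of calls were higher when the interval only had to exclude equal levels.

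The fourth comparison asked how leaves frozen after acclimation differed from leaves frozen without it. The leaves differed in both directions, with 2793 unigenes called higher and 2323 lower in those acclimated before, 6.26% of the 81786 compared. Those called higher held 23.1% of counts in the acclimated and frozen library and 8.01% in the unacclimated frozen one. Those called lower held 2.55% and 10.03%. Abundant unigenes again leaned to the higher side, with 228 higher and 64 lower at 100 FPKM or more, while at 1 to 10 FPKM 959 were higher and 1340 lower. Under 1 FPKM 422 were higher and 301 lower, so the lean did not follow abundance throughout. Here the direction of the balance depended on scaling. With libraries scaled by total counts 1960 unigenes were called higher and 3639 lower, so that 35.01% of calls were higher against 54.6% with TMM and 63.4% with median-of-ratios factors. Scaling by totals moved the log2 ratios in this comparison by a median of -0.26 relative to TMM, and median-of-ratios factors moved them by 0.10. The share of higher calls was also under 50% when the interval only had to exclude equal levels (49.2%) and under the FPKM rule (33.0%). FPKM is itself scaled by total counts. For freezing alone against control the shift of totals against TMM was 0.16, and no other shift relative to TMM exceeded 0.10.

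Against the control, the whole sequence of acclimation and freezing gave the most calls of the 5 comparisons, 5586 higher and 4125 lower, or 12.1% of the 80023 compared. The higher unigenes went from 6.88% of control counts to 33.1%, and the lower ones from 29.3% to 8.10%. Of the higher unigenes, 1223 had no count in the control. Under the FPKM rule 47.8% of calls were higher.

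**Figure D2:**
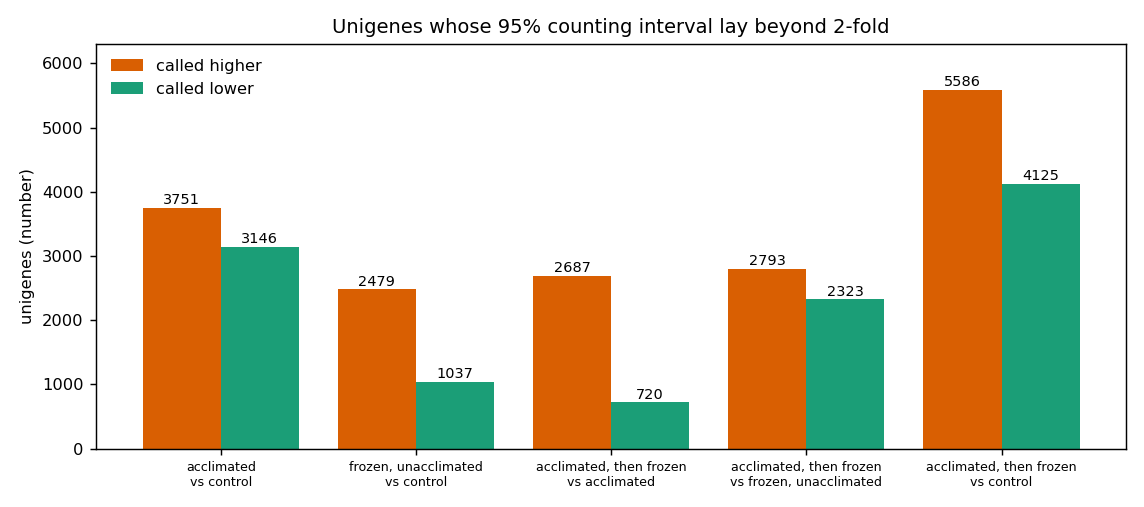
Number of unigenes (vertical axis) called higher (orange) or lower (green) in each of the 5 comparisons between libraries, by the rule that the 95% counting interval lies beyond 2-fold. Both comparisons of a freezing step (2479 against 1037, and 2687 against 720) lean to higher calls, and the bars carry no error because there is 1 library per treatment.

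Whether freezing acted alike with and without acclimation was examined through a pair of ratios that share no library. Many of the unigenes called higher at freezing were shared by both states. In both comparisons 1222 unigenes were called higher, 49.9% of those called without acclimation and 46.4% of those called after it among the 65765 compared in both, where independent lists of these sizes would share 98.0. In a simulation of unchanged unigenes with counting error alone the shared number was 0, and with an assumed spread of 40% between libraries it was 92.2. The 1222 unigenes had a median of 0.859 FPKM in the control, 1.47 FPKM after acclimation, 15.4 FPKM after acclimation and freezing and 13.2 FPKM after freezing alone. Fewer of the unigenes called lower at freezing were shared: 82 were called lower in both, against 10.3 for independent lists and 96.2 in the simulation with an assumed spread. The assumed 40% lies above the common spread of 30.1% fitted by the additive model. The unigenes called lower by freezing alone had a median log2 ratio of -0.52 (-0.28 with zeros at the limit) in the acclimated state, whereas those called higher had a median of 1.89 (1.65). Those called lower had a median of 5.07 FPKM in the control but already 1.61 FPKM after acclimation. It was 0.810 FPKM after acclimation and freezing and 0.936 FPKM after freezing alone. This left less room for a further lower call, so the small sharing does not show that freezing lowered different unigenes. The set was chosen on the control library, which adds to that gap.

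Across the 48004 unigenes with at least 10 counts, the log2 ratios of the pair had a Pearson r of 0.38 and a Spearman rho of 0.28. Across the 23772 with at least 100 counts they were 0.61 and 0.34. Unigenes are not independent replicates, so no p is given. The difference between the freezing responses was itself estimated for each unigene. Its 95% counting interval lay beyond 2-fold for 1306 unigenes whose response was lower after acclimation than without it, and for 975 whose response was higher. This was run with TMM only. Total counts moved the freezing ratios by a median of 0.16 without acclimation and -0.07 after it. The balance of 1306 and 975 may therefore depend on scaling. Of the 2479 unigenes called higher by freezing alone, 607 (24.5%) had a response lower by this measure after acclimation, 60 had a higher one, and 1812 (73.1%) met neither limit. Of the 2687 called higher by freezing after acclimation, 404 (15.0%) had a higher response after acclimation and 88 a lower one. Each of these sets was chosen on a ratio that enters the difference, so a lean towards a weaker response in the other state is partly built in. The 2479 unigenes also had a higher median before freezing in the acclimated library, 1.54 FPKM against 0.585 FPKM in the control. After freezing the medians were 6.26 FPKM with acclimation and 7.53 FPKM without it. A lower response can therefore reflect a level already raised before freezing, although choice on the control adds to that gap.

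The effect of acclimation was followed in the same way, in the unfrozen state and at the freezing step, again through ratios with no library in common. Much of the difference that acclimation made was still present when both states were frozen. Of the 3751 unigenes called higher after acclimation, 88.3% were also higher in the frozen leaves that had been acclimated than in those that had not, and 1536 were called so, with a median log2 ratio of 1.23 over the whole set (1.21 with zeros at the limit). Of the 3146 called lower, 88.1% were lower at the freezing step and 909 were called so, with a median of -1.32 (-1.15). Independent lists would share 152 higher and 106 lower unigenes, and the simulation with an assumed spread of 40% gave 95.7 and 98.9. The direction that shared more turned with scaling. With total counts 1159 higher and 1248 lower unigenes were shared, and with median-of-ratios factors 1736 and 782. The 1536 higher unigenes had a median of 5.59 FPKM in the control, 27.7 FPKM after acclimation, 27.9 FPKM after acclimation and freezing and 8.21 FPKM after freezing alone. The 909 lower ones had medians of 12.2, 2.32, 1.88 and 10.3 FPKM in the same order of libraries. Across unigenes with at least 100 counts, Pearson r was 0.68 and Spearman rho was 0.69, and with at least 10 counts they were 0.45 and 0.48.

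**Figure D3:**
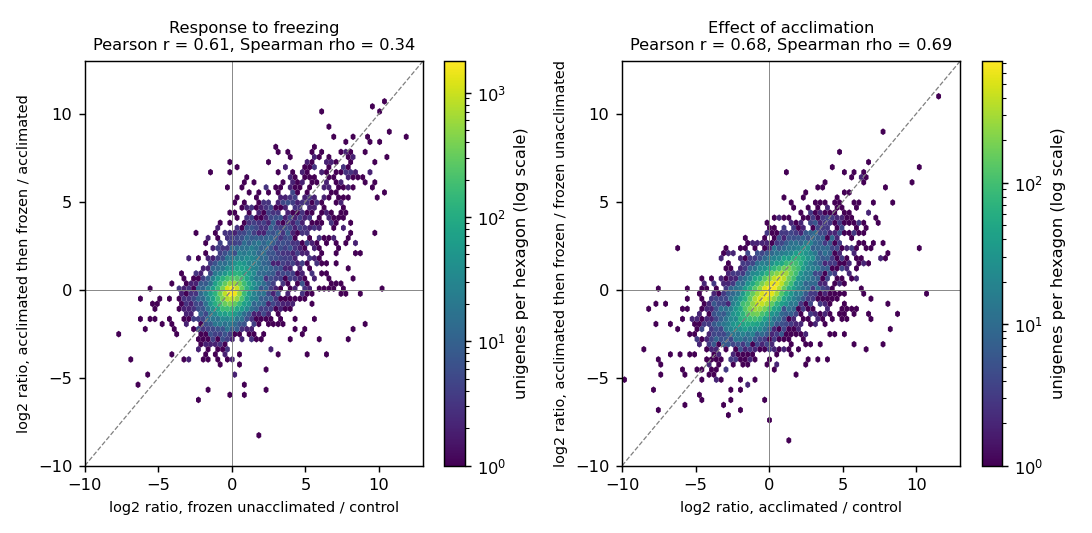
Log2 ratios of the 23772 unigenes with at least 100 counts, with colour giving the number of unigenes per hexagon on a log scale and the dashed line marking equal ratios. The left panel sets freezing after acclimation (vertical) against freezing without it (horizontal), with r of 0.61 and rho of 0.34, and the right panel sets the effect of acclimation in frozen leaves (vertical) against its effect in unfrozen leaves (horizontal), with r of 0.68 and rho of 0.69.

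**Figure D4:**
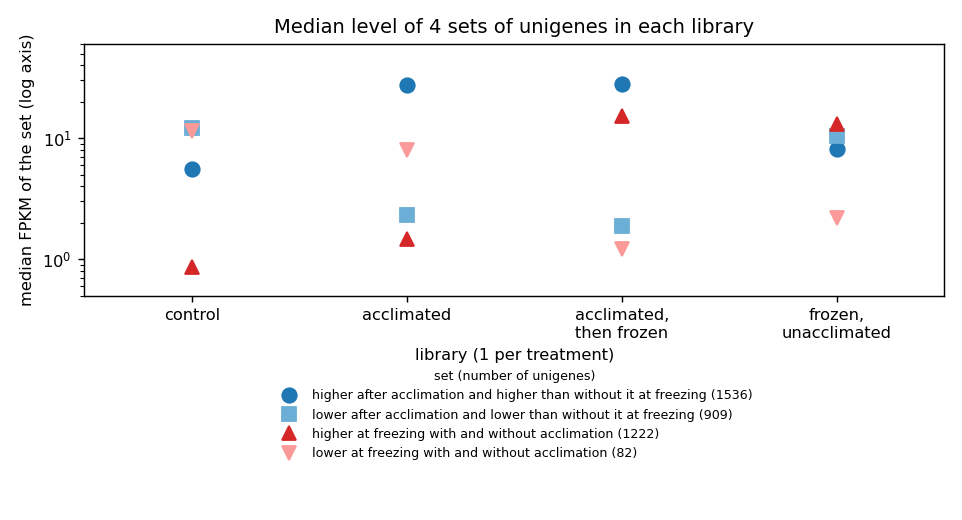
Median FPKM (vertical axis, log scale) in each of the 4 libraries for 4 sets of unigenes that were called in the same direction in a pair of comparisons sharing no library. The sets were chosen on these libraries, so the points show levels and are not independent evidence of direction; the 1222 unigenes higher at both freezing steps lie at 0.859 and 1.47 FPKM in the unfrozen libraries and at 15.4 and 13.2 FPKM in the frozen ones.

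Acclimation and freezing alone were also compared for the unigenes they changed relative to the common control. Called higher in both were 651 unigenes, 17.8% of those called higher after acclimation and 28.9% of those called higher after freezing alone among the 71129 compared in both, and 471 were called lower in both. Independent lists would share 116 and 45.9. Both comparisons use the same control library, whose chance deviations enter both. With counting error alone the simulated overlap was 0.15 in each direction, and with an assumed spread of 40% it was 492 higher and 329 lower. Part of the overlap may therefore come from the shared control, which cannot be split. That 40% is above the common spread of 30.1% fitted by the additive model. Opposite calls were fewer, with 23 unigenes higher after acclimation and lower after freezing alone and 38 the other way. The shared control also lowers the number of opposite calls, so their small number is not independent evidence that the treatments acted alike. The number that unrelated lists would give was not worked out for opposite calls.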

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

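The tests of depth and of RNA from elsewhere in the third paragraph were chosen after the result was seen. The other tests below were chosen before, but the intervals used to decide on length at the freezing step and on the classes of abundance were added after their values were seen. For length at the freezing step the condition for a cause was set in advance on the longest class and the condition against it on every class, and the longest class was taken to decide after all values were seen.

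Freezing gave opposite calls for 49 unigenes in the acclimated and the unacclimated state: 42 were called lower after acclimation and higher without it, and 7 the other way. Acclimation gave opposite calls for 72 unigenes before and at the freezing step, of which 55 were higher at 4 °C and lower at freezing, and 17 the other way. In the same pairs of comparisons, calls in one direction were 1222 higher and 82 lower for freezing, and 1536 higher and 909 lower for acclimation. The number of opposite calls that unrelated lists would give was not worked out, so these counts do not show more discordance than unrelated lists. With 1 library per treatment these differences were not tested.

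More unigenes were detected in leaves frozen without acclimation than in any other library, 70594 at equal depth against 63730 to 64284. Greater depth is argued against, since that library held 14345704 counts, fewer than the control (15781435) and the acclimated library (15179341). After all libraries were thinned to 14024558 counts the excess over the next library was 9.82%. Thinning could hardly have removed it, because it took more counts from those 2 deeper libraries. Crowding of the other libraries by a few abundant unigenes is also argued against, since the excess was 8.21% after the 1000 most abundant unigenes were removed. RNA of another organism or tissue stays open: 33.5% of the excess lay in unigenes without a count in the other 3 libraries, a share between the limits set for deciding, and no sequences were used here. Broader transcription after sudden freezing, or a difference of this single library, stays open as well and was not tested.

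At both freezing steps more unigenes were called higher than lower, 70.5% without acclimation and 78.9% after it. Library scaling is argued against as the whole cause, since the lowest share under the other scalings was 67.7%. Unigene length is argued against as the whole cause, since in the longest of 3 equal length classes the shares were 73.0% (exact 95% interval 71.2 to 74.7%) without acclimation and 77.6% (75.9 to 79.2%) after it, although the 96 calls of the shortest class without acclimation, at 62.5% (52.03 to 72.2%), were too few to meet the limit set for every class. The intervals of the shares by length treat called unigenes as independent draws and hold no spread between plants. Under the rule that an interval only excludes equal levels the shares were 52.6% and 48.0%, a smaller lean without acclimation and none after it. Induction by freezing is a candidate explanation that stays open, together with the spread between plants.

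In acclimated leaves the median log2 ratio of unigenes at 10 FPKM or more exceeded that at 1 to 10 FPKM by 0.29 before freezing and by 0.40 at the freezing step, but under 1 FPKM the median was 0.05 and -0.52, so the order did not run through all classes before freezing. Scaling moves all classes together, and under total counts the median at 10 FPKM or more was -0.12 at the freezing step with an excess of 0.39, so only the difference between classes is meant. Chance values of the compared libraries setting the classes are argued against. With classes from the other libraries the smaller excess was 0.24 (bootstrap 95% interval over unigenes 0.21 to 0.27). That interval treats unigenes as independent and holds no spread between plants. The other libraries also differ in acclimation, so this test cannot exclude that acclimation itself moved unigenes between classes. Unigene length stays open as part of the cause, since the excess within the length classes went down to 0.18, between the limits set for deciding. Acclimation itself stays open as untested, with 1 library each.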

How the results depend on the processing

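Counts of calls stayed within 1.5 times under scaling by total counts or by median-of-ratios factors, with at least 10 counts over the libraries, with at least 1 FPKM in a library, and with an implied length of at least 500 bases (the last chosen after seeing the data). The interval rule set the counts. Counts by rule run in the order acclimation, freezing alone, freezing after acclimation, frozen with against frozen without acclimation, and the whole sequence against control. An interval beyond 4-fold called 1709, 1280, 1208, 958 and 3009 unigenes. All of them were also called in the same direction under the 2-fold rule, which must hold because the rules are nested. An interval that only excluded equal levels called 24750, 19368, 18469, 22887 and 27616. A log2(FPKM + 1) difference of at least 1, which ignores depth and admits scarce unigenes, called 11751, 8388, 7172, 12085 and 15914. The side of the majority turned in 7 cases. The share of higher calls was 35.01% for frozen with against frozen without acclimation under total counts. Where the interval only excluded equal levels it was 48.4% for acclimation, 48.0% for freezing after acclimation and 49.2% for frozen with against without. Under the FPKM rule it was 46.8% for acclimation, 33.0% for frozen with against without and 47.8% for the whole sequence. FPKM is scaled by total counts, and for frozen with against without that scaling alone gave the 35.01% above. What else set these shares was not tested. Pearson r between the freezing responses was 0.199 with no count filter, 0.605 with at least 100 counts and 0.472 with a prior count of 5. For acclimation it was 0.245, 0.678 and 0.575. Overlaps of calls stayed within 1.5 times under the scalings and the count filter. For acclimation before and at the freezing step, however, the larger side turned, from 1536 higher and 909 lower with TMM to 1159 and 1248 with total counts. In acclimation against control the 4 named unigenes kept their direction and call under both scalings and the 4-fold rule. They had been picked for the most extreme intervals of that comparison, so this outcome was built in and is no check. Depth limits scarce unigenes: 45833 had fewer than 10 counts, too few for most to pass an interval rule. With 1 library per treatment no library could be left out. The alternatives for gene lists were not run, since no names were paired with identifiers, and the pseudocount for a table without counts did not apply. An additive fit of acclimation and freezing (edgeR's quasi-likelihood test, 1 residual degree of freedom, chosen after seeing the data) called 5867 unigenes for acclimation at an adjusted p under 0.05, 3297 higher and 2570 lower, and 1607 for freezing, 1436 higher and 171 lower. It assumes that the effects add, and its calls are for each factor over both states of the other. No paired analysis of plants was possible because each treatment had 1 pooled library. The additive fit compares each factor within the states of the other.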

Other observations

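Some unigenes were called in one direction at 4 °C and in the opposite direction at the following freezing step. Called lower after acclimation and higher at the following freezing step were 237 unigenes, with medians of 10.5 FPKM in the control, 1.39 FPKM after acclimation, 9.67 FPKM after acclimation and freezing and 14.2 FPKM after freezing alone. The mirror group held 245 unigenes, with medians of 1.36, 16.1, 2.39 and 2.76 FPKM in the same order. Both groups rest on the single acclimated library, which enters both of their comparisons with opposite sign. With counting error alone the simulated sizes were 0.2 and 0. With an assumed spread of 40% between libraries they were 474 and 307, so groups of this size do not exceed what such a spread gives. The 40% is an assumption, and the additive fit gave a common spread of 30.1%, with any interaction of acclimation and freezing counted in. No simulation of these groups was run at that spread, so whether they exceed it is unknown. Unigene c100903.graph_c0 (771, 2, 233 and 646 counts) belongs to the first of these groups by its calls, and after acclimation and freezing it was still called lower than in the control (log2 ratio -1.46, 95% interval -1.68 to -1.25). The time of day of each harvest is not given in the sources used here, and a daily rhythm was not tested.

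Both hypotheses below were tested as set out before their values were seen. The first was that the relation between the freezing responses rests on the unigenes called in either comparison. Among the 20651 unigenes with at least 100 counts that were called in neither, Pearson r was 0.21 and Spearman rho 0.19, just above the limit of 0.2 set in advance, so the question stays undecided. Leaving out called unigenes narrows the range and lowers r by itself. The same step for the effect of acclimation left r at 0.54 over 17448 unigenes.

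The second was that unigenes from one assembly component respond alike, as they may where copies of a gene share sequence, reads or regulation. In 1114 components with a pair of unigenes of at least 100 counts, Spearman rho between the members was 0.46 for acclimation, 0.35 for freezing alone, 0.37 for freezing after acclimation and 0.44 for frozen with against frozen without acclimation. Pairs matched on abundance gave -0.03, -0.02, 0.02 and 0.04, and the smallest excess was 0.34. For acclimation 108 pairs were called in one direction together and 11 in opposite directions. Counts of called unigenes may therefore count some genes more than once, and shared reads and shared regulation cannot be separated here.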
